A study of Rattus norvegicus with 24 samples.

How the data were processed

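Whole hearts were profiled in 24 rat samples on 1-colour Affymetrix arrays, with biotin-labelled RNA made from total heart RNA per the labels' protocols. The samples belonged to 4 groups of 6: a control group and groups labelled with 10, 30 and 100 µg of zinc sulfate. The labels give 16 weeks for every heart without saying whether this is an age or a length of exposure, and they state no volume for the doses. Sample numbers differed throughout and paired no samples. The labels do not state that each number is a separate animal, so p-values measure the spread between these samples. Batch, date, sex and strain were not given in the sources used here.

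The deposited values are intensities on a linear scale, 1 per probe set and array, as the values themselves show: the highest was 12553, and 59103 values (15.5%) were below 0, so background or mismatch signal had been subtracted before deposit. The software and settings that made these intensities were not given in the sources used here. Column medians of the deposited intensities ran from 19.51 to 43.11, a 2.21-fold range. The table held 15923 rows, 57 of them with names of control probe sets. Of the rows, 12789 had 1 gene symbol in the annotation table used, 312 had several and 2822 had none listed.

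Before any test between groups, the row names were checked against the values, because rows named for abundant heart genes were near background. Pairs of rows named for the same gene, for genes with at most 5 rows, were compared with random pairs across the 24 arrays. The levels of rows in all fixed gene lists were placed among all rows, and those given in the text are sarcomere, ventricular myocytes, atrial myocytes, oxidative phosphorylation, ribosomal proteins, red blood cells, T and B lymphocytes, and lung epithelium. The names failed the check by pairs. No gene, pathway or cell type is therefore reported as changed, and a row is given by its label only, with at most 2 rows per direction for 1 comparison. Planned steps that need gene identity were left out: tests of the gene lists, 1 probe set per gene, the 3-prime to 5-prime ratios and their use as a covariate. The rule for named genes, which would have named zinc, antioxidant, natriuretic and clotting genes and the strongest changes per comparison, was not applied for the same reason.

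The design fixed before the data were examined assumed that linear values would not be negative. Because some were, and because column medians differed by more than the limit set for normalization, the 15866 rows without control names were quantile normalized on the linear scale, negative values were set to 0, and log2(value + 16) was taken. A log2 change is on that scale and understates the change of dim rows. Since the row names failed the check, the rows left out by name need not be the control probe sets. Control probe sets may remain among the rows that were normalized and tested. After normalization, 710 rows were at or below 0 on every array. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 4 group means, all 24 arrays). The comparisons were each dose against control, all exposed groups against control, the doses against each other, any difference between the groups, and a slope over group order. Adjusted p-values are Benjamini-Hochberg values within a comparison, and 0.05 was the threshold.

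Array-level measures were the first and second principal components, the deposited median, and the root-mean-square log2 distance of each array from the mean of the other arrays of its group. Groups were compared by 2-sided exact permutation tests over all splits of 6 against 6, whose smallest possible p is 0.0022. For the distance, group-centred arrays were split again and the distances recomputed. In 500 simulated sets of unchanged groups this test gave p below 0.05 in 4.8% with 6 arrays against 6, but in 9.8% with 4 against 6, so the test of the dim arrays as a cause used distances times the square root of (n - 1)/n and centred arrays times that of n/(n - 1), which gave 3.0%; with 5 against 6 the rates were 10.6% and 5.8%. The 24 array-level tests were adjusted together. Whole profiles were compared by the mean squared distance between groups minus that within groups, in a 1-sided exact test over 924 splits, adjusted over the 6 pairs of groups. Agreement of fold changes between doses was set against 100 simulated data sets of unchanged groups sharing the controls, and was recomputed with the controls split 3 and 3 in all 20 ways. The simulations shuffled the residuals of all arrays together, so simulated controls spread as much as exposed arrays.

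The limma step was tested on 20 simulated data sets made from the residuals of the real arrays, with 200 of 15866 rows changed in the 100 µg group. For 100 µg against control it recovered 14.3% of the rows changed by 0.25 on the log2 scale, 52.3% at 0.50, 80.4% at 0.75 and 92.6% at 1, with a mean of 4.9 false calls per data set. Changed rows were drawn from all tested rows, including the 710 at or below 0 on every array, and changes were added on the log2 scale. Those 710 rows have no spread, which favours recovery, and a fall below the floor cannot occur in the data. Residuals of all arrays were shuffled together, so unequal spreads between groups were not kept. The recovered shares therefore describe these simulations and may not hold for the real arrays. The number of arrays limits the precision. Alternatives were the normalization, centring, the pseudocount (1 or 64), the brighter 0.5 of the rows, the variance model, array weights, an adjusted p threshold of 0.10, only the compared groups in the fit, a slope over µg, and leaving out each array. Alternatives chosen after the data were seen were a common median for each array, array brightness as a covariate, all rows, and leaving out the 4 arrays with a deposited median below 25. The array-level measures were recomputed only under alternatives chosen at that point. Other calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.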

Results

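Whole-heart RNA was measured in 24 rat samples, 6 in each of a control group and groups labelled 10, 30 and 100 µg of inhaled zinc sulfate, all at 16 weeks. The series asks whether subchronic inhalation of this soluble metal salt alters the heart of healthy rats. Each array gave 1 intensity for each of 15923 probe set rows. The arrays resembled each other closely, with correlations between arrays of 0.973 to 0.997 over the deposited values. Deposited medians averaged 34.86 ± 4.20 in controls, 31.70 ± 8.35 at 10 µg, 31.12 ± 7.25 at 30 µg and 32.92 ± 8.39 at 100 µg (SD, n = 6 each).

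The gene names attached to the rows failed the check by pairs against the measured signal. Examples, chosen after their values were seen, were transcripts abundant in heart muscle. The row named for Ckm, the muscle creatine kinase, had a mean intensity of -13.8 ± 7.51, and that for Fabp3, the heart fatty acid binding protein, -12.8 ± 6.06 (SD, n = 24 arrays). The rows named for Myl2, the ventricular regulatory light chain of myosin, were at 5.60 ± 3.41 and 19.0 ± 11.1, and that for the myoglobin gene Mb was at 21.3 ± 11.9. The rows named for Tnnt2, cardiac troponin T, were at -1.61 ± 8.98 and 3.68 ± 6.90. The row named for Ryr2, the calcium release channel of cardiac sarcoplasmic reticulum, was at -37.6 ± 25.2. Other rows with heart gene names were bright, such as those for Tnni3, cardiac troponin I, at 1600 ± 358 and Myl3 at 1370 ± 329. Rows named for Gapdh were at 139 ± 36.3, 76.0 ± 20.6 and 140 ± 35.0. A row named for Gcg, which encodes the pancreatic hormone glucagon, was at 4360 ± 645, and 1 of the rows named for Slc1a2, a glutamate transporter of brain, was at 8230 ± 982 while the other was at 28.4 ± 8.27. Probe sets differ in affinity, so these levels are descriptive and do not rank the genes by abundance.

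Levels of rows in 49 gene lists fixed before the data were examined are described in the same way, with list medians from the 13.7 to the 78.5 percentile of all rows. The 8 lists given here were chosen after their levels had been seen and include both extremes. Rows named for sarcomere genes had a median at the 52.4 percentile, those for ventricular myocytes at 39.5, atrial myocytes at 63, oxidative phosphorylation at 42.7 and ribosomal proteins at 25.7. The 6 rows named for red blood cell genes were at 13.7, those for T and B lymphocytes at 67.4 and the 10 for lung epithelium at 78.5. The check that does not rest on levels across probe sets was the correlation between rows of the same gene. Across the 24 arrays, 2644 pairs of rows named for the same gene had a mean correlation of 0.00037 (SE 0.0050), against 0.0056 for 9999 random pairs, and the levels of the paired rows correlated at 0.021. The 18 rows named for the bacterial and phage hybridisation controls had mean intensities of -9.21 to 166 and a mean pairwise correlation of -0.021. Because of these correlations the comparisons between groups are given as numbers of rows and as properties of whole profiles, with no gene, pathway or cell type assigned to them.

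**Figure D1:**
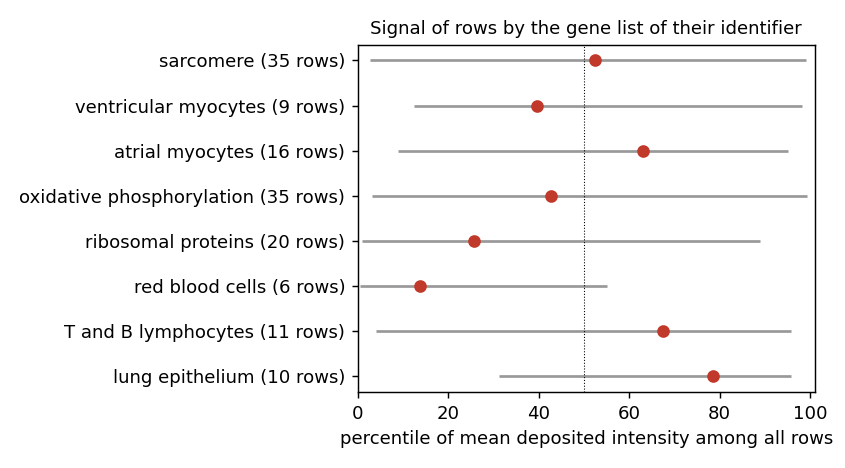
Points mark the median, and lines the lowest to highest value, of the percentile of mean deposited intensity among all rows (x axis) for rows named for each of 8 gene lists (y axis, number of rows in brackets); the dotted line is the middle of all rows. The lung epithelium list had a median at 78.5 and the sarcomere list at 52.4.

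Hearts of the 100 µg group against control were the main comparison. No row passed an adjusted p of 0.05 with limma, and the smallest adjusted p was 0.15. At unadjusted p below 0.05 there were 1583 rows of 15866 where uniform p-values give 793 and other splits of the same arrays gave a median of 601, with 790 higher and 793 lower at 100 µg. The p-values cannot be uniform here, since the 710 rows at or below 0 on every array show no difference. In this comparison 1511 rows had a limma p above 0.95. The count from uniform p-values is therefore only a rough reference. The rows with the smallest p, none of them past the threshold, were the row labelled 1376527_at, with a log2 difference of 0.58 (SE 0.11), and 1386309_at, with 0.37 (SE 0.07), and, lower at 100 µg, 1375996_at with -0.61 (SE 0.12) and 1375912_a_at with -0.66 (SE 0.13), each with an adjusted p of 0.15. Differences were small: the median absolute log2 difference was 0.09, 7 rows differed by more than 1, and the median 95% interval reached 0.24 to either side. With the brighter 0.5 of the rows alone, 3 rows passed the threshold, and 2 passed with each array centred on its median. Without control replicate 3, 1 row passed.

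The lower doses gave no row past the threshold. At 10 µg no row passed the threshold in limma (smallest adjusted p 0.15), and 1359 rows were at unadjusted p below 0.05, 685 higher and 674 lower, where uniform p-values give 793 and other splits of the same arrays gave a median of 662. Uniform p-values are a rough reference here too. At 30 µg no row passed (smallest adjusted p 0.45), and 735 rows were at unadjusted p below 0.05, with 377 higher and 358 lower, where the median of other splits was 585. Without normalization between arrays the counts at unadjusted p below 0.05 were 718 at 10 µg and 421 at 30 µg. For 10 µg, 2 rows passed with the brighter 0.5 of the rows and 2 with centring on the median, and 1 passed without 30 µg replicate 46. All exposed samples together against control gave no row past the threshold (smallest adjusted p 0.21) and 985 rows at unadjusted p below 0.05, 519 higher and 466 lower (median of other splits 690); 1 row passed without 30 µg replicate 43.

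Tests over all 4 groups also gave no row past the threshold in limma. For any difference between the groups the smallest adjusted p was 0.13, with 1832 rows at unadjusted p below 0.05 (median of other splits 695), or 600 without normalization between arrays. For the slope over group order it was 0.23, with 1160 rows at unadjusted p below 0.05, 580 higher and 580 lower with dose (median of other splits 697). With the slope taken over µg in place of group order, 4 rows passed and 1979 were at unadjusted p below 0.05. Without control replicate 3 the test of any difference gave 1 row, and without 10 µg replicate 24 it gave 4.

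The doses were also compared directly. For 100 µg against 10 µg no row passed in limma (smallest adjusted p 0.071), and 2046 rows were at unadjusted p below 0.05, 983 higher and 1063 lower. For 100 µg against 30 µg no row passed (smallest adjusted p 0.059), and 2133 were at unadjusted p below 0.05, 1007 higher and 1126 lower. For 30 µg against 10 µg no row passed (smallest adjusted p 0.076), with 830 at unadjusted p below 0.05, 395 higher and 435 lower. Medians of other splits were 871, 714 and 825 in the same order. Without normalization between arrays the counts were 595, 655 and 317. For 100 µg against 10 µg the count was 1259 with array weights and 1263 without the 4 dim arrays, and for 30 µg against 10 µg it was 505 with centring on the median. The main fit shared an estimate of the spread over groups whose median row SD ran from 0.159 in controls to 0.215 at 10 µg. With only the compared groups in the fit, 100 µg against 10 µg gave 1558 rows and 100 µg against control 2005. Array weights gave 2104 for 100 µg against control. Which of these 2 counts is larger thus depends on how the spread is modelled. With the brighter 0.5 of the rows, 66 rows passed for 100 µg against 10 µg and 26 for 100 µg against 30 µg. Without 10 µg replicate 24, 67 rows passed for 100 µg against 10 µg, and without 100 µg replicate 64, 37 did, with 58 for 100 µg against 30 µg.

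**Figure D2:**
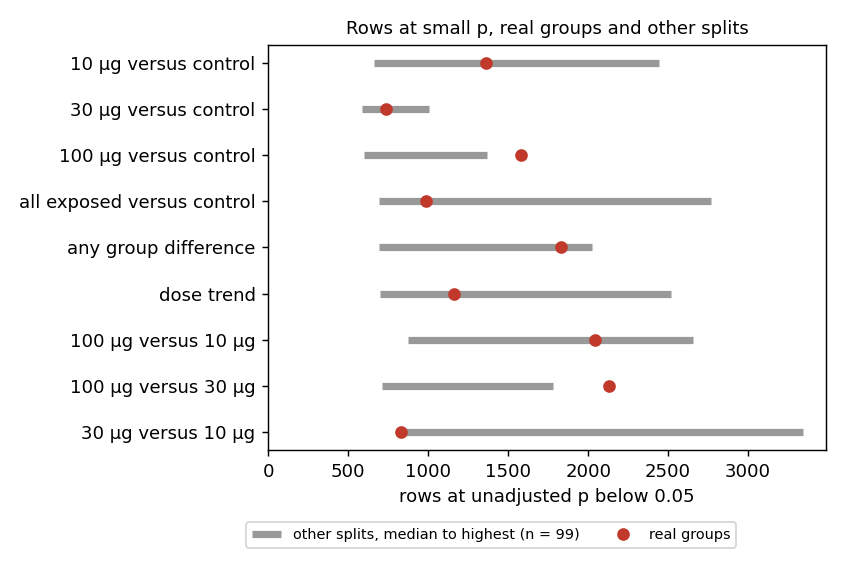
Number of rows at unadjusted p below 0.05 (x axis) for each comparison (y axis); points are the real groups of 6 arrays, and grey bars run from the median to the highest of 99 other splits of the same arrays. The real count lay above the bar for 100 µg against control (1583, highest other 1368) and for 100 µg against 30 µg (2133, highest other 1783).

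Whole profiles of the 100 µg hearts stood apart from those of the controls. On the first principal component, with 16.6% of the variance, the 100 µg arrays averaged 11.9 ± 8.17 and the controls -2.53 ± 2.19 (SD, n = 6 each; exact permutation p = 0.0022, adjusted p = 0.018), and each of the 6 arrays at 100 µg lay above all 6 controls. The 30 µg arrays averaged -5.89 ± 8.05 (exact p against control 0.39, adjusted p 0.67) with a mean below that of the 100 µg arrays (exact p = 0.0065, adjusted p = 0.039), though 30 µg replicate 46, at 6.73, lay above 100 µg replicates 61, at 6.37, and 64, at 3.85. The 10 µg arrays averaged -3.44 ± 20.3 (exact p against control 0.86, adjusted p 0.89). On the second component, with 10.2% of the variance, the 10 µg arrays averaged 8.90 ± 10.2 and the controls -6.30 ± 3.38 (exact p = 0.0022, adjusted p = 0.018). The squared distance between groups exceeded that within groups for 100 µg against control (exact p = 0.0022, adjusted p = 0.013) and for 100 µg against 30 µg (exact p = 0.0043, adjusted p = 0.013), and not past the threshold for 10 µg (adjusted p 0.12) or 30 µg (adjusted p 0.12) against control. Without normalization between arrays, the components were those of another decomposition: the exact p for 100 µg against control was 0.44 on the first and 0.0022 on the second. On the second, 10 µg against control had an exact p of 0.29. For 100 µg against 30 µg the exact p was 0.75 on the first and 0.011 on the second. The squared distance then had an exact p of 0.21 for 100 µg against control and 0.37 for 100 µg against 30 µg, where the distance between groups was the smaller one, with a difference of -0.0033.

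Control arrays lay closer to each other than the 10 µg arrays did. The distance of an array from the rest of its group averaged 0.236 ± 0.0133 log2 units in controls, 0.304 ± 0.0322 at 10 µg, 0.266 ± 0.0223 at 30 µg and 0.269 ± 0.0294 at 100 µg (SD, n = 6 each). The permutation p against control, over all splits of group-centred arrays, was 0.0022 at 10 µg (adjusted p 0.018), 0.011 at 30 µg (adjusted p 0.053) and 0.048 at 100 µg (adjusted p 0.18). With distances rescaled for group size, an alternative chosen after the data were seen, it was 0.0022, 0.024 and 0.061. Only the 10 µg difference passed after adjustment over the 24 array-level tests. Deposited medians did not differ past the threshold between any dose and control (exact p 0.45, 0.29 and 0.61 for 10, 30 and 100 µg; adjusted p 0.70, 0.54 and 0.86).

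**Figure D3:**
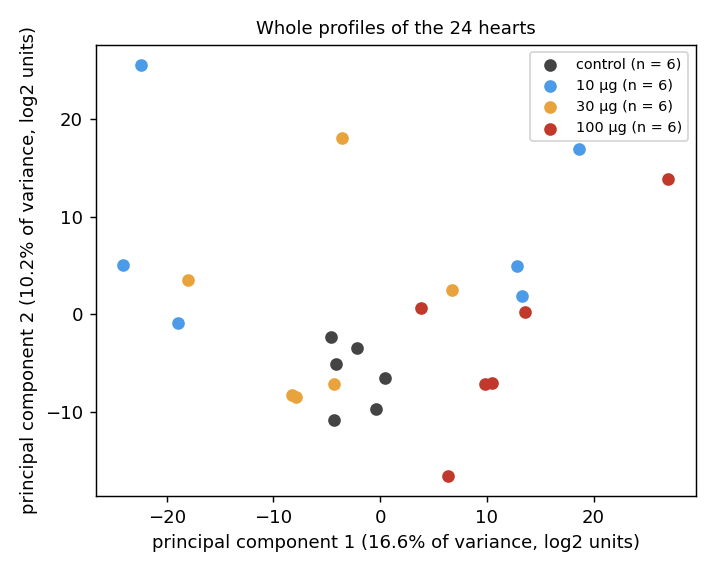
First principal component (x axis) and second (y axis) of the normalized log2 values, 1 point per array, coloured by group (n = 6 each), with the share of variance on each axis. All 6 arrays at 100 µg lie to the right of the 6 controls, which lie close together, while the 10 µg arrays spread from -24.1 to 18.6 on the first component.

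The agreement of fold changes between doses lay within the range of simulated unchanged groups, but that range cannot decide whether shared controls explain it. The simulations mixed residuals of control and exposed arrays. Real controls varied less, with a median row SD of 0.159 log2 units against 0.215, 0.187 and 0.185 at 10, 30 and 100 µg. Less variable controls give a lower correlation through sharing alone, so the simulated values may be too high a reference. Across rows, which are not independent replicates, the correlation was 0.548 for 10 and 30 µg, where simulated unchanged groups gave 0.502 ± 0.11 (SD of 100 simulations), 0.405 for 10 and 100 µg against 0.523 ± 0.10, and 0.317 for 30 and 100 µg against 0.505 ± 0.094. The highest simulated correlations were 0.736, 0.737 and 0.746. The covariances were 0.0129, 0.0119 and 0.00792 in the same order, against simulated means of 0.0107 ± 0.0033, 0.0114 ± 0.0036 and 0.0106 ± 0.0031. With the controls split so that no control was shared, the correlations were 0.164, 0.112 and 0.0058. These were not set against simulations.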

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

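The tests of the row names, of the 4 dim arrays and of a graded effect, and all splits of the samples, were chosen or worded after the results they bear on had been seen; the tests of brightness and of single arrays on the first component were set down before their results.

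The first principal component differed between dose groups: the 100 µg arrays averaged 11.9 and the 30 µg arrays -5.89, with an exact permutation p of 0.0065 for the difference. Without normalization between arrays, on the first component of that decomposition, it was 0.75, so the call on a first component depends on the normalization. Components of differently processed values need not match. On the second component of that decomposition the 100 µg and 30 µg arrays did differ, as given above, while the squared distance between whole profiles did not separate them. The loss on the first component alone therefore does not show that the difference vanished. In 40 groups of 6 arrays tested for an outlying array, over array-level measures and the 4 rows given by label, 0 arrays stood out, where chance flags about 5 in 100. Those 4 rows were picked for small p, which favours little spread within groups, so that rate does not apply to them.

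The displacement of the 100 µg arrays from controls on that component was weighed against technical causes. With the slope on array brightness within groups removed, the exact permutation p was 0.0022 and the difference 16.6 in place of 14.4, which argues against brightness as the cause. With each 100 µg array left out in turn and the component recomputed, the highest exact p was 0.0022, the smallest that 5 against 6 can give, as the 5 arrays kept lay on 1 side of all controls each time. The recomputed loadings correlated with those of all arrays at 0.948 (without replicate 65) or higher, and on the component of all arrays the difference without 1 array was 11.4 or more. These values argue against any 1 array as the whole cause. The 10 and 30 µg arrays averaged -3.44 and -5.89, both below the control mean of -2.53 and on the side away from 100 µg. Their exact permutation p against control was 0.86 and 0.39, so these differences lie within the spread. An effect of zinc sulfate graded with dose therefore stays open and cannot be told apart from one limited to the highest dose. The component also varied within a single dose, from -24.1 to 18.6 at 10 µg, so it does not follow dose alone. What else it follows was not tested. The labels name no batch, so a batch that follows the groups may remain, and an effect of the exposure also remains open.

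The larger distances of exposed arrays from their own group might come from the 4 dim arrays, none of which is a control. Since the distance grows as a group shrinks, it was rescaled for group size in this test. Without the dim arrays the permutation p at 10 µg was 0.015, with a difference of 0.0502 log2 units in place of 0.0616, which argues against them as the whole cause there. At 30 µg it was 0.069 (difference 0.0179 in place of 0.0274, p with all arrays 0.024), and at 100 µg it was 0.28 (difference 0.0159 in place of 0.0298, p with all arrays 0.061). At these 2 doses the difference became smaller and fewer arrays were left, so dim arrays cannot be told apart from other causes. Unlabelled batches within exposed groups and variation in response between animals were not tested.

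Other splits of the same arrays bear on the counts of rows. For the rows past the adjusted threshold the real count was 0 in all 9 comparisons, so all 100 of 100 splits give as many by construction, and these splits decide nothing about chance. The highest count in another split was 18, 1 and 1 for 10, 30 and 100 µg against control, 10 for all exposed, 3 for any difference, 2 for the slope, 161 for 100 µg against 10 µg, 2 for 100 µg against 30 µg, and 680 for 30 µg against 10 µg. The split with 680 rows set 10 µg replicates 21, 22 and 23 and 30 µg replicates 41, 43 and 44 against the remaining arrays of both groups, with first component means of -16.6 and 7.25. The split with 161 rows exchanged 10 µg replicate 24 with 100 µg replicate 64. No cause for either was tested.

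For rows at unadjusted p below 0.05, fewer than 5 of 100 splits were as large for 100 µg against control (1583, highest other 1368, 1 of 100 splits), for 100 µg against 30 µg (2133, highest other 1783, 1 of 100) and for any difference (1832, highest other 2026, 2 of 100). Adjusted over the 9 comparisons these shares were 0.045, 0.045 and 0.060. For the first 2 counts the only split as large was the real grouping. Their share of 0.01 was thus the smallest that 100 drawn of 462 distinct splits can give. No other drawn split was as large, but this test, chosen after the counts were seen, does not exclude chance. For the third count the adjusted share was above 0.05. Without normalization between arrays the counts were 1082, 655 and 600, and 12, 29 and 35 of the same 100 splits were as large, so on those values chance was not excluded for any of these counts. On normalized values chance was also not excluded for 10 µg against control (1359, highest other 2444, 15 of 100), 30 µg against control (735, highest other 1003, 11), all exposed (985, highest other 2767, 16), the slope (1160, highest other 2517, 12), 100 µg against 10 µg (2046, highest other 2657, 7) or 30 µg against 10 µg (830, highest other 3346, 50).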

How the results depend on the processing

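The alternatives for array-level measures, and scaling to a common median, brightness as a covariate, all rows and leaving out the dim arrays, were chosen after the data were seen. Of 124 settings of the counts past the adjusted threshold other than leaving out 1 array, 109 gave 0 rows as the reported analysis did. Centring on the median gave 2 rows for 10 µg and 2 for 100 µg against control and 1 for 100 µg against 10 µg. The brighter 0.5 of the rows, where fewer rows are tested, gave 2, 3, 66 and 26 rows for 10 µg and 100 µg against control and 100 µg against 10 µg and 30 µg. Array weights gave 1 for 100 µg against control and 9 against 30 µg. A threshold of 0.10 gave 40, 28 and 1 for 100 µg against 10 µg, 100 µg against 30 µg and 30 µg against 10 µg. The fit of the 2 compared groups alone gave 20 for 100 µg against 30 µg, the slope over µg gave 4, and a common median gave 1 for 100 µg against control. Leaving out 1 array gave 0 to 1 rows for 10 µg, 100 µg and all exposed against control and 30 µg against 10 µg, 0 to 4 for any difference, 0 to 67 for 100 µg against 10 µg, 0 to 58 for 100 µg against 30 µg, and 0 for the other comparisons. For 30 µg against 10 µg the arrays whose loss gave 1 row were control replicate 1 and 10 µg replicates 24 and 26. For 100 µg against 10 µg control replicate 3 and 10 µg replicate 26 gave 1 row each. For 100 µg against 30 µg control replicates 1 and 3 and 10 µg replicates 22 and 23 gave 4 each, 10 µg replicate 24 gave 5, and 10 µg replicate 21, 30 µg replicate 46 and 100 µg replicate 62 gave 1 each. Apart from the number of rows tested, the cause was not tested.

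Counts at unadjusted p below 0.05 stayed within 1.5 times in 98 of 115 settings and in all 216 that left out 1 array. Staying within that limit does not keep the order of the counts between comparisons. Without normalization they were 718 and 421 for 10 and 30 µg against control, 600 for any difference, 595, 655 and 317 for 100 µg against 10 µg and 30 µg and for 30 µg against 10 µg. With the brighter 0.5 of the rows they were 824, 398, 896, 513, 1188, 620 and 379 for 10, 30 and 100 µg against control, all exposed, any difference, the slope and 30 µg against 10 µg. They were 1442 and 1485 for 100 µg against 10 µg and 30 µg, which stayed within 1.5 times. Only 0.5 of the rows were tested there, so lower counts come with fewer rows and do not by themselves show a weaker result. As shares of the rows tested, the counts were larger than over all rows in every comparison except 30 µg against 10 µg. The dimmer rows include those at the floor on every array, which cannot give a small p. Centring gave 505 for 30 µg against 10 µg, array weights 1259 and leaving out the dim arrays 1263 for 100 µg against 10 µg, and the slope over µg 1979.

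The correlations of fold changes became 0.164, 0.112 and 0.0058 with split controls, 0.277 and 0.181 for 10 and 30 µg with 100 µg in the brighter rows, and 0.541 and 0.467 for the same pairs without normalization. Components of differently processed values were compared by their p-values only. Without normalization between arrays the first component no longer separated 100 µg from controls (exact p 0.44) or from 30 µg (exact p 0.75), the second separated 100 µg from controls (exact p 0.0022) and from 30 µg (exact p 0.011) and not 10 µg from controls (exact p 0.29), the distance at 30 µg had p 0.36, and the whole-profile separation had exact p 0.21 for 100 µg against control and 0.37, reversed, against 30 µg. The distance at 100 µg had permutation p of 0.14 and 0.056 with pseudocounts 1 and 64, 0.054 with a common median, 0.061 rescaled for group size and, not rescaled, 0.071 without the dim arrays. The second component separated 100 µg from 10 µg with pseudocount 1 (exact p 0.015). Distances differed between 100 µg and 10 µg with pseudocount 64 (permutation p 0.039) and the brighter rows (0.050), and between 30 µg and 10 µg with pseudocount 64 (0.035), the brighter rows (0.041) and a common median (0.035). The cause was not tested. Signal limits the dim rows: 15.5% of values were below 0. Not run, since they need gene identity, were the list tests with all their alternatives, 1 probe set per gene, the 3-prime to 5-prime covariate and all alternatives for named genes.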

Other observations

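The tests in this part were chosen after the row names had been seen to disagree with the values. Rows named for abundant heart genes were near background, and 3 explanations were weighed. Row names out of step with the values are a candidate explanation: pairs of rows named for the same gene correlated no better than random pairs, with a difference in mean correlation of -0.0052. Arrays that failed to hybridise are argued against by the lowest correlation between arrays, 0.973. An annotation table of another array was weighed by the rows named for hybridisation controls, whose names stand in the value table itself. Their mean intensities were -9.21 to 166 and their mean pairwise correlation was -0.021. If only the annotation were wrong, these rows should correlate with each other, provided that the controls gave signal. Whether they gave signal was not tested, and rows near background correlate little under any name. These rows therefore cannot decide about the annotation table. Which row belongs to which probe set stays open, and no biological explanation was tested.

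The values kept some order along the table, since levels of neighbouring rows correlated at 0.36. The 8 neighbouring rows with the highest mean pairwise correlation, 0.867, began at table position 10951 and had mean intensities from 75.1 to 5468. No row was renamed from its position.

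The 10 µg arrays fell on both sides of the controls on the first component: samples 21, 22 and 23 were at -18.9, -22.4 and -24.1, and samples 24, 25 and 26 at 13.3, 12.8 and 18.6, while the controls lay between -4.64 and 0.423.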
